A study of Mus musculus with 4 samples.

How the data were processed

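Expression was measured by RNA sequencing of total RNA from mouse fetal pancreas at 4 stages, with 1 sample per stage. The series describes the material as pancreatic epithelium, and how the epithelium was isolated is not given in the sources used here. Per the submitters' processing notes, reads were processed with HISAT2 version 2.0.5 and the mm10 genome build. The counting tool, the gene annotation and the number of libraries per stage are not given in the sources used here. The deposited values are FPKM per Ensembl gene, named as averages per the file headers, for 54532 gene IDs. Symbols, coordinates and exon lengths came from GENCODE M21, which uses the same build, and 54495 IDs had a symbol there.

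Groups were the stages in the labels. Each sample was divided by a median-of-ratios factor from the 9884 genes at 1 FPKM or more in every stage (0.988 at E11.5, 1.03 at E13.5, 1.03 at E15.5 and 0.961 at E18.5). Differences are on the log2(FPKM + 1) scale, which understates the change of low genes. With 1 sample per stage the planned analysis had no test. A gene counted as higher or lower by a rule of size, at least 2-fold apart with the higher value at 5 FPKM or more, among 14828 genes at 1 FPKM or more in any stage. For 44 gene lists fixed before the data were examined, the median difference and the members past the rule were computed. Each median was placed among 10000 random lists of the same size matched on expression in 20 bins.

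The named genes followed a rule fixed before the data were examined. For each comparison it took the 8 genes in each direction with the largest log2 difference, past the rule of size and at 10 FPKM or more, without genes lacking a symbol, predicted genes, pseudogenes, histones and mitochondrial genes. It added, from each list described, up to 4 members with the largest difference past the rule and up to 2 with the highest value, 12 marker genes, and the 5 most abundant genes of each sample. Which of the list members that this rule allows are described was settled after their values were seen. Sst at E13.5 against E11.5, and Foxa2 and the marker genes of other tissues in the closing section, were named outside the rule after their values were seen. Not every gene that the rule took is described, and Serpina1d and Serpina1e at E15.5 against E13.5 are among those left out.

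After the data were examined, the deposited FPKM values multiplied by exon length were found to be sums of whole reads of 2 libraries per stage. For each stage the FPKM denominators of both libraries were estimated from low genes. Each mean was split where only 1 pair of whole reads gave it within 0.75 of its last printed place and at most 0.05 such pairs were expected by chance. Between 94.9% and 95.1% of the genes attempted were split, and genes with too many reads for a unique answer were left whole. In 28 simulations with denominators in ratios from 0.550 to 0.999, 648918 splits were right and 0 wrong. The simulated means used the same exon lengths and formula as the split, so they do not give the error rate in these files. In the deposited values, from 1204 genes at E13.5 to 1238 at E11.5 were given by no pair of whole reads. The estimated reads were 0.898 times the denominator in library 1 at E11.5 and 1.26 times in library 1 at E15.5, so the denominators were not plain read totals. The libraries of a stage differed by 1.23 to 1.33 times counting error. This recovery rests on the values, and no label states it.

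The log2 values of 12790 genes split in all 8 libraries were compared with limma 3.58.1 in R 4.3.3, with a mean-variance trend and Benjamini-Hochberg adjustment at 0.05, chosen after the data were examined. The 2038 measured genes that could not be split, which include most abundant enzymes and hormones, had no test. On simulated data for E13.5 against E11.5 with 12790 genes, limma called 98% of genes raised 2-fold, 90% of those lowered 2-fold, 42% of those raised 1.5-fold and 9 of 12590 unchanged genes. The simulated libraries were drawn independently with the same assumed dispersion for all genes and no added spread between stages. These rates therefore do not give the false calls in the real data, where variation between embryos may be missing from the spread within a stage. In a simulation of the rule of size for the same comparison with 7035 genes, 50 of 50 genes raised 2.5-fold, 48 of 50 lowered 4-fold, 0 of 50 raised 1.5-fold and 0 of 6835 unchanged genes were called. Between the libraries of a stage, 15 of 5890 genes at E11.5, 27 of 5694 at E13.5, 33 of 5884 at E15.5 and 23 of 6276 at E18.5 were 2-fold apart. Of the genes past the rule of size that limma could test, it called the same direction in 616 of 618 higher and 685 of 689 lower at E13.5 against E11.5. Both rest on the same values, so this agreement is not independent support.

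A fold against a stage listed at 0 is a lower bound from 3 reads over the 2 libraries, which covers counting error only. Gapdh, which all cells use, was at 1.74 FPKM at E18.5 and 12.3 at E13.5, and genes with near-identical copies had low values, so a value of 0 was read only as listed at 0. Sharing was measured as the percentage of 50-base windows of a gene's longest transcript found in transcripts of other genes. Transcript lengths were those of the APPRIS principal transcripts in GENCODE M21. Alternatives were other scalings, pseudocounts, minimum values and folds, list members and, added after the data were examined, limma, leaving out each recovered library and leaving out E11.5. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used.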

Results

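Gene expression was measured by RNA sequencing in samples described as pancreatic epithelium of wild-type C57BL/6 mouse fetuses from E11.5 to E18.5 (E, embryonic day), with E13.5 and E15.5 between them. Consecutive stages and the ends of the span were compared. The labels gave 1 sample per stage, and each sample held the authors' mean FPKM (fragments per kilobase of transcript, scaled by a denominator per library) for every gene. The recovered denominators were not plain read totals. The values showed that each mean averaged 2 libraries counted in whole reads. The estimated reads of these libraries were 1.67e+07 and 1.63e+07 at E11.5, 1.80e+07 and 1.59e+07 at E13.5, 1.58e+07 and 1.37e+07 at E15.5, and 1.45e+07 and 1.44e+07 at E18.5. All levels below are scaled FPKM. A value after ± is the SD of the recovered libraries (n = 2). Levels without one belong to genes whose mean could not be split into whole reads and which had no test. Either the gene had too many reads for a unique answer, or no pair of whole reads gave its mean. No label says that the libraries came from separate embryos, so the SDs and the limma p-values measure only the spread between these libraries, which can be technical. At E15.5 and E18.5 the ratios of Y-linked to Xist reads argued against separate pools, as described in the closing section. Limma p-values that involve these stages are therefore not a measure of variation between embryos.

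Acinar digestive enzymes took 0.00307% of all FPKM at E11.5, 1.92% at E13.5, 23.7% at E15.5 and 17.3% at E18.5. The islet hormones took 0.0953%, 0.886%, 0.696% and 8.02% at the same stages. Haemoglobin transcripts took 3.15% at E11.5 and 0.0780%, 0.0552% and 0.137% later. The most abundant transcript at E11.5 was the embryonic globin Hbb-y at 5202 FPKM, followed by Stmn1, which shares 35.3% of its 50-base windows with other genes and is uncertain, at 3553, and the imprinted Nnat at 3454. At E13.5 it was Spp1, which encodes the secreted phosphoprotein osteopontin, at 4419. The lipase-related Pnliprp1 was the most abundant at E15.5 and E18.5, at 47651 and 27856. Genes at 1 FPKM or more numbered 12361 at E11.5, 11761 at E13.5, 11976 at E15.5 and 12353 at E18.5.

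Over the 14828 genes that reached 1 FPKM in any stage, Pearson's r of the log2 values was 0.949 between E13.5 and E15.5, 0.922 between E15.5 and E18.5, and 0.856 between E11.5 and E13.5. It was lowest between E11.5 and E18.5, at 0.765. These correlations run across genes, which are not independent replicates. Of 4442 genes past the rule of size, which takes a 2-fold difference with the higher value at 5 FPKM or more, between any of the stages, 1497 were highest at E11.5, 304 at E13.5, 1329 at E15.5 and 1312 at E18.5. With libraries set to the same total, the number of changed genes highest at E11.5 was 3607, the number of changed genes highest at E13.5 was 922, and the number of changed genes highest at E15.5 was 524.

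**Figure D1:**
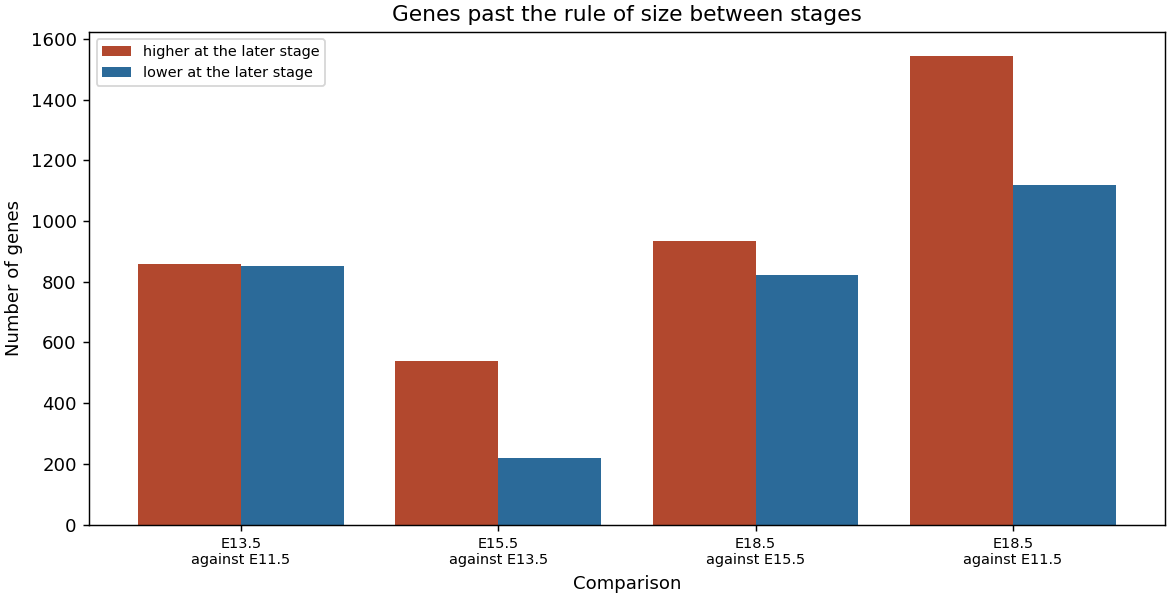
Number of genes past the rule of size, at least 2-fold apart with the higher value at 5 FPKM or more, for each comparison of stages (bars, higher and lower at the later stage). E18.5 against E11.5 gives the most genes, 1545 higher and 1120 lower.

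The first comparison set E13.5 against E11.5, and factors of pancreatic progenitors were higher at E13.5. The E11.5 sample also held transcripts of other tissues, described below. A smaller share of pancreatic cells there cannot be told apart from a rise with stage. This limit holds for the progenitor, exocrine and endocrine genes in every comparison against E11.5. Pdx1, which is required for pancreas formation (ENSMUSG00000029644, chromosome 5, 147269959 to 147275848, mm10), rose from 2.94 ± 0.502 to 79.1 ± 1.43, with a log2 difference of 4.35 (SE 0.0903, limma adjusted p = 2.07e-07). Nkx6-1 rose from 1.496 ± 0.149 to 53.0 ± 0.109, and Ptf1a, a factor of early pancreatic and later acinar cells (ENSMUSG00000026735, chromosome 2, 19445663 to 19447501), rose from 0.604 ± 0.119 to 30.4 ± 1.17. Nkx2-2 rose from 0.385 ± 0.0336 to 25.2 ± 0.630, while Sox9, a factor of the progenitor and duct epithelium, was at 49.5 ± 0.715 and 123. Of 27 measured progenitor factors 18 were higher and 1 lower by the rule of size, with a median log2 difference of 2.32, and limma tested 17 of them, of which 15 rose and 1 fell, with the same counts adjusted over the list alone. Limma counts of list members take the adjusted p at any fold, by which 67.8% of all tested genes were called in this comparison, 55.8% at E15.5 against E13.5, 68.5% at E18.5 against E15.5 and 74.4% at E18.5 against E11.5. Epithelial identity genes were higher in 18 of 24 members and lower in 1 (limma, 13 tested, 13 rose and 0 fell, as many adjusted over the list alone). Among the higher ones were Cdh1, which encodes the adhesion protein E-cadherin, at 6.29 ± 0.361 and 64.8, the keratin gene Krt8 at 197 and 807, and Epcam at 295 and 768. Beside these groups, markers of mesenchyme were lower in 17 of 27 members and those of neural crest and glia in 8 of 15.

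Genes of the exocrine lineage were higher at E13.5 in part. The 10 genes of the tip, the progenitor domain that gives rise to acinar cells, were all higher by the rule of size, with a median log2 difference of 3.58 (limma, 4 tested, 4 rose and 0 fell, as many adjusted over the list alone). Cpa1, a carboxypeptidase gene of tip and acinar cells (ENSMUSG00000054446, chromosome 6, 30639218 to 30645363), was at 2.21 ± 0.0815 and 1540.3. Acinar digestive enzymes were higher in 11 of 34 members with 0 lower and 23 neither (limma, 8 tested, 4 rose and 1 fell, as many adjusted over the list alone). The chymotrypsinogen gene Ctrb1 was at 0.125 ± 0.0869 and 865, Pnliprp1 at 1.19 and 1446, Clps, which encodes the cofactor of pancreatic lipase, at 0.862 ± 0.334 and 538, Cel at 0.144 ± 0.0162 and 144, and Cela1 at 0.982 ± 0.0514 and 222. Acinar transcription factors were higher in 9 of 13 members (limma, 10 tested, 8 rose and 2 fell, as many adjusted over the list alone). Rbpjl, a partner of Ptf1a in acinar cells, was at 0.274 and 33.2 ± 0.299, and Bhlha15, the acinar factor Mist1, rose from 0.119 ± 0.0355 to 7.13 ± 0.511. Accessory genes of acinar secretion were higher in 7 of 23 members and neither in 16 (limma, 18 tested, 8 rose and 3 fell, as many adjusted over the list alone). Serpini2 was listed at 0 at E11.5 and was at 77.7 ± 2.55 at E13.5, at least 1323-fold higher against a floor of 3 reads over both libraries.

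Endocrine genes were higher at E13.5 in part. Neurog3, which starts endocrine differentiation (ENSMUSG00000044312, chromosome 10, 62133090 to 62134763), was at 0.430 ± 0.0538 and 134. The endocrine factor genes Pax4 and Fev rose from 0.248 ± 0.0770 to 67.0 ± 1.25 and from 0.257 ± 0.0284 to 68.33 ± 2.30. Endocrine progenitor genes were higher in 8 of 26 members and lower in 4 (limma, 20 tested, 11 rose and 5 fell, as many adjusted over the list alone). The lower ones included Neurod1, a factor of endocrine cells and neurons, at 197 and 38.7 ± 2.10. Islet hormones were higher in 9 of 11 members and lower in 1 (limma, 5 tested, 4 rose and 1 fell, as many adjusted over the list alone), the lower one being Sst, the somatostatin gene, at 18.8 ± 0.368 and 1.06 ± 0.343. Gcg, which encodes glucagon (ENSMUSG00000000394, chromosome 2, 62474530 to 62483650), was at 211 and 2402. Ins2, which encodes insulin (ENSMUSG00000000215, chromosome 7, 142678656 to 142743381), was listed at 0 at E11.5 and was at 29.0 ± 5.17 at E13.5, at least 459-fold higher. Iapp, the gene of islet amyloid polypeptide, was at 1.96 ± 0.153 and 101 ± 7.05. Endocrine secretory granule genes were higher in 9 of 26 members and lower in 5 (limma, 16 tested, 9 rose and 7 fell, as many adjusted over the list alone). Chgb, a granin gene, was at 20.4 ± 1.86 and 817, and Snap25, a gene of neuronal and endocrine exocytosis, fell from 31.7 ± 0.614 to 1.55 ± 0.189.

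Markers of several other tissues were lower at E13.5, while the gut and stomach list went both ways and the endothelium list was mostly below 1 FPKM. Mesenchymal genes were lower in 17 of 27 members with 0 higher (limma, 22 tested, 0 rose and 19 fell, as many adjusted over the list alone), and the proteoglycan gene Lum fell from 42.0 ± 0.593 to 0.339 ± 0.0346 and Twist1 from 14.7 ± 0.787 to 0.105 ± 0.0575. The erythroid list had 14 of 15 members lower and a median log2 difference of -3.96 (limma, 11 tested, 0 rose and 10 fell, as many adjusted over the list alone). The embryonic globin genes Hbb-y and Hbb-bh1 were at 5202 and 125 ± 12.3 and at 1288 and 1.62 ± 0.243. Genes of neural crest and glia were lower in 8 of 15 members (limma, 10 tested, 0 rose and 8 fell, as many adjusted over the list alone), with the neuronal Stmn2 at 129 and 0.565 ± 0.00676 and Tubb3 at 427 and 13.8 ± 0.383. Mesothelial genes were lower in 4 of 7 members (limma, 5 tested, 0 rose and 5 fell, as many adjusted over the list alone), and Upk3b fell from 17.5 ± 0.959 to 0.163 ± 0.126. Of 15 liver genes 7 were lower and 5 higher (limma, 10 tested, 2 rose and 8 fell, as many adjusted over the list alone), with Alb, the albumin gene, at 65.4 ± 1.81 and 0.552 ± 0.149 and Ttr at 44.4 and 322. The leukocyte list had 4 of 15 members lower and 1 higher (limma, 14 tested, 1 rose and 13 fell, as many adjusted over the list alone), and Coro1a fell from 25.2 ± 0.252 to 1.25 ± 0.124. Of the 20 names of the endothelium list only 3 were measured, of which 1 was higher and 0 lower, with a median log2 difference of 0.48, and of 11 gut and stomach genes 1 was higher and 2 lower, with a median of 0.40 (limma, 10 tested, 6 rose and 4 fell, as many adjusted over the list alone). The endothelial gene Pecam1, below 1 FPKM throughout, was at 0.160 ± 0.0654 and 0.0132 ± 0.00516.

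Among the largest differences downward was Oc90, an otoconial protein gene, which was at 1252 at E11.5 and listed at 0 at E13.5, at least 28709.9-fold lower. Others were the cartilage gene Cnmd at 268 and 0.232 ± 0.127, the homeobox gene Six2 at 191 and 0.0914 ± 0.0106, and the neuronal genes Gap43 at 520.4 and 2.38 ± 0.618, Tagln3 at 295 and 1.03 ± 0.0369 and Stmn3 at 214 and 0.838 ± 0.142. Sncg fell from 191 ± 10.1 to 0.720 ± 0.0629, with a log2 difference of -6.81 (SE 0.120, limma adjusted p = 1.33e-07). None of the 42 cell cycle genes passed the rule of size, while limma called 10 that rose and 9 that fell among 27, with 10 and 10 adjusted over the list alone. The share called in either direction was near the 67.8% over all tested genes. Mki67, the gene of the proliferation antigen Ki-67 (ENSMUSG00000031004, chromosome 7, 135689784 to 135716361), fell from 13.7 ± 0.225 to 8.23 ± 0.0698.

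In all, 857 genes were higher and 851 lower at E13.5 by the rule of size. Limma on the recovered libraries called 3960 genes that rose and 4709 that fell among 12790 tested, 987 and 1424 of them at least 2-fold. Other pseudocounts, minimum levels and folds gave 282 to 1635 genes higher and 336 to 1699 lower.

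**Figure D2:**
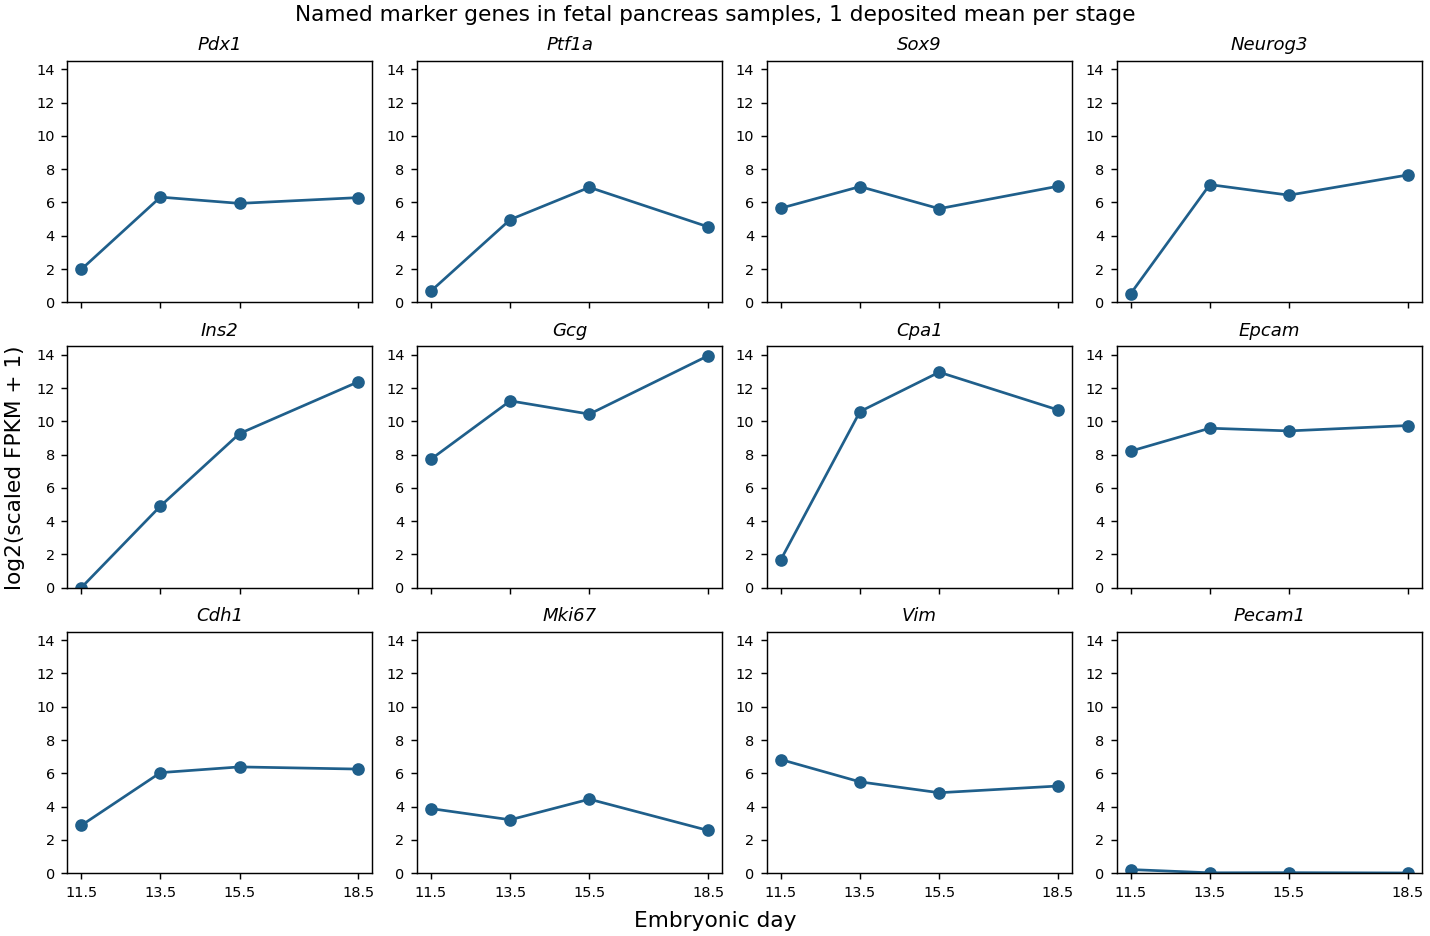
Levels of 12 marker genes by embryonic day (horizontal axis), as log2(scaled FPKM + 1) (vertical axis), with 1 point per stage for the authors' mean and lines that only join the points. Ins2 reaches 5328 FPKM at E18.5, Ptf1a and Cpa1 are highest at E15.5, and the endothelial gene Pecam1 is highest at E11.5, at 0.160 FPKM.

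Between E13.5 and E15.5 the digestive enzymes of acinar cells were higher in 27 of 34 members, with 0 lower and a median log2 difference of 4.36 (limma, 8 tested, 7 rose and 0 fell, 8 and 0 adjusted over the list alone). Ctrb1 was at 865 and 38008, Pnliprp1 at 1446 and 47651, Clps at 538 and 10259.9, and Cel at 144 and 1435. The elastase genes Cela2a and Cela3b were at 2.35 ± 0.274 and 779.8 and at 2.77 ± 0.0888 and 557. Trypsinogen genes were among the largest differences, with Prss1 at 0.570 ± 0.390 and 1698, Try10 at 0.691 ± 0.289 and 1266, Try5 at 9.40 ± 1.31 and 1492 and Prss3 at 0.308 ± 0.0747 and 480.0. The amylase gene Amy2a1 was at 0.807 ± 0.106 and 506 and Amy2a3 at 0.683 ± 0.229 and 283. These trypsinogen and amylase genes share sequence with near-identical copies, from 36.6% of windows in Try10 to 93.0% in Amy2a1 and all in Amy2a3, as does Cela2a with 26.9%, and their levels are uncertain.

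Factors and secretory machinery of acinar cells were higher at E15.5 as well. Ptf1a rose from 30.4 ± 1.17 to 119 ± 0.0133, with a log2 difference of 1.94 (SE 0.0668, limma adjusted p = 9.27e-06). Bhlha15 rose from 7.13 ± 0.511 to 41.8 ± 1.20, and Rbpjl was at 33.2 ± 0.299 and 171. Acinar transcription factors were higher in 6 of 13 members (limma, 10 tested, 8 rose and 1 fell, as many adjusted over the list alone), and tip genes in 8 of 10 (limma, 4 tested, 4 rose and 0 fell, as many adjusted over the list alone), with Reep5 at 49.6 and 392. Accessory genes of acinar secretion were higher in 15 of 23 members (limma, 18 tested, 16 rose and 0 fell, as many adjusted over the list alone). The water channel gene Aqp8 rose from 0.638 ± 0.105 to 89.7 ± 4.49, and Sycn, which encodes the zymogen granule protein syncollin, rose from 4.33 ± 1.60 to 94.8 ± 5.10. Aqp12 was listed at 0 at E13.5 and was at 23.5 ± 0.00368 at E15.5, at least 307-fold higher. Genes of protein folding and export in the endoplasmic reticulum were higher in 17 of 43 members with 0 lower (limma, 18 tested, 16 rose and 0 fell, 17 and 0 adjusted over the list alone). Among them were Sdf2l1 at 141 ± 4.57 and 675, Ssr2 at 373 and 812, and Herpud1 at 35.9 ± 0.602 and 131. Ribosomal protein genes were higher in 20 of 85 members with 0 lower (limma, 39 tested, 36 rose and 0 fell, 37 and 0 adjusted over the list alone). Several of these groups depended on the scaling. With libraries set to the same total, the median log2 difference of acinar transcription factors, E15.5 against E13.5, was 0.46 in place of 1.01. In the same way the median log2 difference of ER protein folding and export, E15.5 against E13.5, was 0.26 in place of 0.85, and the median log2 difference of cytosolic ribosomal proteins, E15.5 against E13.5, was 0.25 in place of 0.87.

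Some endocrine progenitor genes were lower at E15.5, and trunk genes lay on both sides. Sox9 was at 123 and 48.5 ± 1.53, Spp1 at 4419 and 1742, and Hhex at 75.6 and 28.9. Trunk genes, those of the bipotent duct and endocrine domain, were lower in 3 of 13 members, higher in 1 and neither in 9 (limma, 9 tested, 2 rose and 4 fell, as many adjusted over the list alone), the higher one being the Notch target Hes1 at 74.9 ± 0.504 and 153. Endocrine progenitor genes were lower in 5 of 26 members with 0 higher (limma, 20 tested, 3 rose and 13 fell, as many adjusted over the list alone). Pax4 fell from 67.0 ± 1.25 to 26.5 ± 0.896, and Insm1 from 22.2 ± 0.736 to 7.73 ± 0.165. Neurog3 was at 134 and 85.9 ± 1.08. Islet hormones were higher in 8 of 11 members and lower in 1 (limma, 5 tested, 3 rose and 2 fell, as many adjusted over the list alone), with Ins2 at 29.0 ± 5.17 and 615, Ins1 at 8.27 and 149, and Sst at 1.06 ± 0.343 and 120.4 ± 1.74. Gcg was at 2402 and 1384. The scaling mattered here, and with libraries set to the same total the median log2 difference of endocrine progenitor, E15.5 against E13.5, was -0.98 in place of -0.42, and the median log2 difference of trunk genes, E15.5 against E13.5, was -0.62 in place of -0.15.

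The largest differences downward included Sfrp5, a Wnt inhibitor gene, which fell from 15.03 ± 0.133 to 0.546 ± 0.0376, with a log2 difference of -3.37 (SE 0.0810, limma adjusted p = 3.21e-06). The actin bundling gene Fscn1 fell from 23.2 ± 1.19 to 2.43 ± 0.0124 and the tetraspanin gene Tspan8 from 13.9 ± 0.778 to 0.924 ± 0.114. Slc38a5, an amino acid transporter gene, was at 745 and 117, Mfap4 at 56.4 ± 0.960 and 7.96 ± 0.961, and Hbb-y at 125 ± 12.3 and 6.82 ± 0.424. The erythroid list as a whole had 1 of 15 members higher and 2 lower (limma, 11 tested, 8 rose and 1 fell, as many adjusted over the list alone), and of 27 mesenchymal genes none passed the rule of size (limma, 22 tested, 9 rose and 2 fell, as many adjusted over the list alone). The leukocyte list had 2 of 15 members higher and 0 lower (limma, 14 tested, 5 rose and 0 fell, as many adjusted over the list alone), and with libraries set to the same total the median log2 difference of leukocyte, E15.5 against E13.5, was -0.03 in place of 0.18. Immediate early genes, which respond to tissue dissociation, were higher at E15.5 in 12 of 20 members (limma, 11 tested, 9 rose and 1 fell, as many adjusted over the list alone), with Fos at 165 and 630.1, Atf3 at 16.6 ± 0.720 and 90.4 ± 2.10 and Ier2 at 425 and 1169. This depended in size on the scaling, and with libraries set to the same total the median log2 difference of immediate early and dissociation stress, E15.5 against E13.5, was 0.66 in place of 1.20. Xist, which is transcribed mainly in females, rose from 3.94 ± 0.0157 to 12.4 ± 0.340, and the Y-linked Eif2s3y fell from 9.44 ± 0.248 to 3.49 ± 0.552. The mix of sexes thus differed between these stages and cannot be told apart from stage. Of 42 cell cycle genes 1 was higher and 1 lower by the rule of size, Mki67, which rose from 8.23 ± 0.0698 to 20.8 ± 0.129, and the cyclin gene Ccnd1, which fell from 31.9 ± 0.0691 to 15.2 ± 0.161. Limma called 4 of 27 that rose and 12 that fell, with 4 and 13 adjusted over the list alone, and the share called was near the 55.8% over all tested genes. With libraries set to the same total the median log2 difference of cell cycle, E15.5 against E13.5, was -0.62 in place of -0.01.

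By the rule of size 540 genes were higher and 219 lower at E15.5, and limma called 3685 that rose and 3455 that fell, 544 and 254 of them at least 2-fold. With libraries set to the same total the counts were 190 higher and 1357 lower, and with the same total without the 100 most abundant genes 356 and 403. Other pseudocounts, minimum levels and folds gave 126 to 1299 higher and 24 to 794 lower.

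At E18.5 endocrine genes were higher than at E15.5. Islet hormones were higher in 9 of 11 members, with a median log2 difference of 3.11 (limma, 5 tested, 3 rose and 1 fell, as many adjusted over the list alone). Ins2 was at 615 and 5328, Ins1 at 149 and 2188, Gcg at 1384 and 15766, and Sst at 120.4 ± 1.74 and 3942. Ppy, which encodes pancreatic polypeptide, rose from 22.2 ± 1.75 to 581 ± 6.48, with a log2 difference of 4.65 (SE 0.230, limma adjusted p = 9.40e-06). Endocrine secretory granule genes were higher in 20 of 26 members with 0 lower (limma, 16 tested, 16 rose and 0 fell, as many adjusted over the list alone), with the granin gene Chga at 96.95 ± 2.36 and 1127 and Scg2 at 25.9 ± 1.12 and 323. The prohormone convertase gene Pcsk2 was at 8.10 ± 0.576 and 74.5. Beta cell maturation genes were higher in 15 of 23 members with 0 lower (limma, 17 tested, 16 rose and 0 fell, as many adjusted over the list alone). The zinc transporter gene Slc30a8 rose from 4.22 ± 0.170 to 87.6 ± 1.505 and G6pc2, an islet glucose-6-phosphatase gene, from 5.71 ± 0.341 to 73.2 ± 0.0180. Endocrine progenitor genes were higher in 13 of 26 members and lower in 1 (limma, 20 tested, 16 rose and 3 fell, as many adjusted over the list alone). Neurog3 was at 85.9 ± 1.08 and 200.5.

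Duct genes were higher in 15 of 31 members and lower in 1, with a median log2 difference of 1.44 (limma, 15 tested, 13 rose and 1 fell, as many adjusted over the list alone). Spp1 was at 1742 and 16980.2, Clu at 581 and 3213, and Anxa5 at 49.0 ± 0.523 and 425, and Tspan8 rose from 0.924 ± 0.114 to 18.7 ± 0.425. Hhex was at 28.9 and 193.

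Acinar genes lay on both sides. Digestive enzymes were higher in 16 of 34 members and lower in 5 (limma, 8 tested, 4 rose and 2 fell, as many adjusted over the list alone). The ribonuclease gene Rnase1 was at 106 ± 10.6 and 3372, the kallikrein gene Klk1 at 26.2 ± 1.33 and 543, Ctrb1 at 38008 and 11964, and Pnliprp1 at 47651 and 27856. Ctrl, a chymotrypsin-like gene, rose from 3.02 ± 0.101 to 88.8 ± 7.93. Tip genes were lower in 9 of 10 members and higher in 1 (limma, 4 tested, 0 rose and 4 fell, as many adjusted over the list alone), with Cpa1 at 7943 and 1649. Acinar transcription factors were lower in 5 of 13 members (limma, 10 tested, 3 rose and 6 fell, as many adjusted over the list alone), and Ptf1a fell from 119 ± 0.0133 to 22.2 ± 1.43 and Bhlha15 from 41.8 ± 1.20 to 11.52 ± 1.20. Accessory genes of acinar secretion were higher in 9 of 23 members, lower in 6 and neither in 8 (limma, 18 tested, 14 rose and 3 fell, as many adjusted over the list alone). Among the higher ones, the zymogen granule gene Zg16 rose from 3.19 ± 0.378 to 156 ± 5.44. Reg3b was listed at 0 at E15.5 and was at 63.0 ± 0.837 at E18.5, at least 576-fold higher. Outside the acinar lists, Scara3 rose from 2.03 ± 0.157 to 60.9 ± 1.45 and the sulfotransferase gene Sult1a1 from 0.411 ± 0.0755 to 31.7 ± 2.53.

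Proliferation genes were lower at E18.5. The cell cycle list had 26 of 42 members lower, 1 higher and a median log2 difference of -1.15 (limma, 27 tested, 1 rose and 26 fell, as many adjusted over the list alone). Mki67 fell from 20.8 ± 0.129 to 4.91 ± 0.615, with a log2 difference of -1.88 (SE 0.0693, limma adjusted p = 3.53e-06), and Top2a, the gene of topoisomerase II alpha, from 29.4 ± 0.169 to 7.82 ± 0.198. Birc5 was at 120.4 and 29.8 ± 0.992 and Ube2c at 273 and 58.7 ± 0.444. Ribosomal protein genes were lower in 74 of 85 members with 0 higher and a median log2 difference of -1.45 (limma, 39 tested, 0 rose and 38 fell, as many adjusted over the list alone). Rplp0 was at 2074 and 881. Rpl7a, which shares 68.0% of its windows with other genes and is uncertain, was at 50.7 ± 26.4 and 3.38 ± 0.384. Mitochondrially encoded genes were lower in 8 of 31 members with 0 higher (limma, 22 tested, 0 rose and 12 fell, 0 and 10 adjusted over the list alone). Replication-dependent histones were lower in 12 of 47 with 0 higher (limma, 45 tested, 3 rose and 28 fell, as many adjusted over the list alone).

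The largest single differences downward belonged to the corticosteroid-binding globulin gene Serpina6 at 3350.0 and 40.9 ± 1.40, the imprinted non-coding H19 at 1239 and 36.8 ± 0.777, and the vitronectin gene Vtn at 271 and 21.9 ± 0.0725, and the vitamin D-binding protein gene Gc was lower too. Aldh1b1, an aldehyde dehydrogenase gene, was at 306 and 27.4 ± 0.235, the ATP receptor gene P2rx1 at 184 and 17.8 ± 0.531, and Afp at 20.6 ± 0.190 and 1.33 ± 0.176. Markers of mesenchyme were higher in 4 of 27 members (limma, 22 tested, 13 rose and 2 fell, as many adjusted over the list alone), with Lum, which rose from 2.15 ± 0.0736 to 11.4 ± 0.0828. Leukocyte genes were higher in 3 of 15 members and lower in 1 (limma, 14 tested, 10 rose and 1 fell, as many adjusted over the list alone), and those of neural crest and glia were higher in 3 of 15 (limma, 10 tested, 5 rose and 1 fell, as many adjusted over the list alone). Xist fell from 12.4 ± 0.340 to 2.504 ± 0.0595 and the Y-linked Eif2s3y rose from 3.49 ± 0.552 to 16.9 ± 0.268. Stage and the mix of sexes therefore cannot be told apart in this comparison either.

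By the rule of size 934 genes were higher and 823 lower, and limma called 4903 that rose and 3852 that fell, 1176 and 807 of them at least 2-fold. Higher and lower counts were 1039 and 534 with libraries set to the same total, and 1114 and 596 with the same total without the 100 most abundant genes. Other pseudocounts, minimum levels and folds gave 230 to 1766 higher and 100 to 1696 lower.

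**Figure D3:**
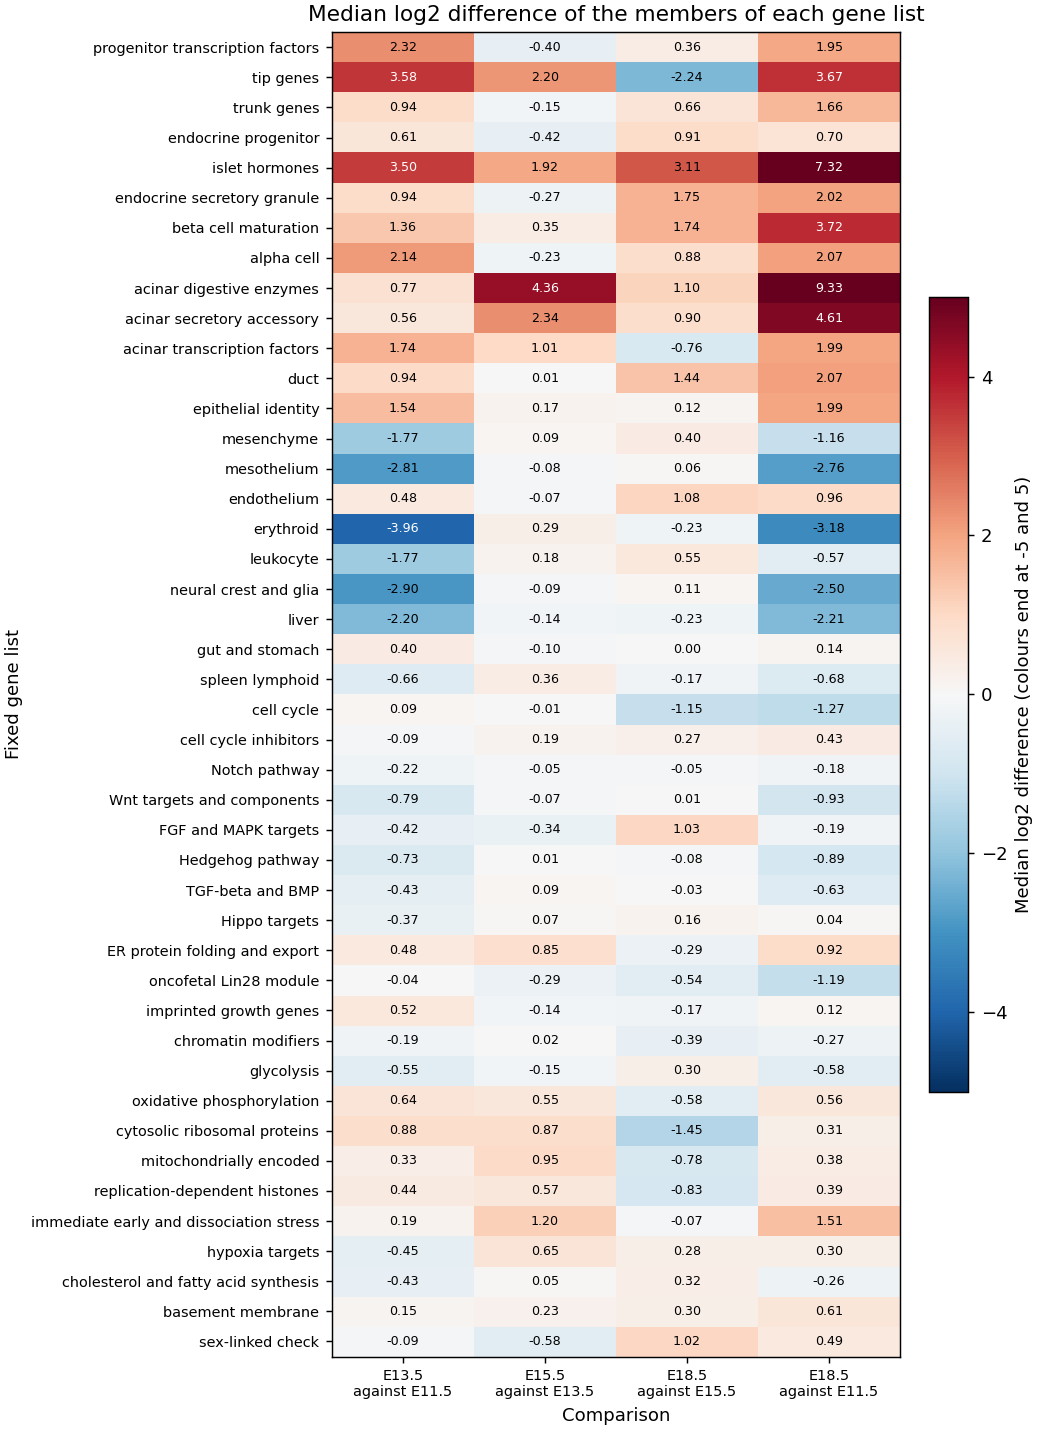
Median log2 difference of the measured members of each of 44 gene lists (vertical axis) in each comparison of stages (horizontal axis), red for higher and blue for lower at the later stage, with the value in each cell. The acinar digestive enzymes reach 4.36 between E13.5 and E15.5, and the cytosolic ribosomal proteins lie at -1.45 between E15.5 and E18.5.

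Over the whole interval, E18.5 against E11.5, digestive enzymes were higher in 28 of 34 members (limma, 8 tested, 8 rose and 0 fell, as many adjusted over the list alone), and all 11 islet hormones were higher (limma, 5 tested, 5 rose and 0 fell, as many adjusted over the list alone). Ins2 and Cela2a were listed at 0 at E11.5 and were at least 84333-fold and 124618-fold higher at E18.5 against the floor of 3 reads. Pnliprp1 was at 1.19 and 27856, Ctrb1 at 0.125 ± 0.0869 and 11964, Cel at 0.144 ± 0.0162 and 3549, and the trypsinogen gene Prss2 at 0.0670 ± 0.0948 and 3329. Accessory genes of acinar secretion were higher in 20 of 23 members (limma, 18 tested, 18 rose and 0 fell, as many adjusted over the list alone), among them Sycn, at least 3578-fold higher. Duct genes were higher in 19 of 31 members and lower in 1 (limma, 15 tested, 13 rose and 1 fell, as many adjusted over the list alone), with the mucin gene Muc1 at 1.41 ± 0.310 and 143. Epithelial identity genes were higher in 20 of 24 members and lower in 1 (limma, 13 tested, 13 rose and 0 fell, as many adjusted over the list alone), with the claudin gene Cldn3 at 71.9 ± 2.63 and 682. Between consecutive stages, 18 were higher at E13.5 against E11.5, 1 at E15.5 against E13.5 and 0 at E18.5 against E15.5. The difference thus lay mostly against E11.5, a sample that also held transcripts of other tissues. Immediate early genes were higher in 12 of 20 members (limma, 11 tested, 9 rose and 2 fell, as many adjusted over the list alone), with Junb at 30.3 ± 0.234 and 471. With libraries set to the same total the median log2 difference of immediate early and dissociation stress, E18.5 against E11.5, was 0.92 in place of 1.51.

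Cell cycle genes and the oncofetal Lin28 module were lower over this interval, and imprinted growth genes were not. The cell cycle list had 27 of 42 members lower (limma, 27 tested, 1 rose and 26 fell, as many adjusted over the list alone), with Rrm2, a ribonucleotide reductase gene, at 179 and 39.7 ± 1.73. The oncofetal Lin28 module had 7 of 13 members lower and 0 higher (limma, 11 tested, 0 rose and 10 fell, as many adjusted over the list alone). Hmga2, a chromatin architectural gene, fell from 15.3 ± 0.486 to 2.68 ± 0.0972, with a log2 difference of -2.15 (SE 0.0506, limma adjusted p = 2.04e-07), and the RNA-binding protein gene Igf2bp1 from 8.22 ± 0.113 to 0.767 ± 0.0774. Of 22 imprinted growth genes 5 were higher and 5 lower (limma, 11 tested, 8 rose and 1 fell, as many adjusted over the list alone), and the median log2 difference of imprinted growth genes, E18.5 against E11.5, was 0.12 and turned to -0.12 with libraries set to the same total. Sox11 was at 53.5 and 0.113 ± 0.0528. The retinoic acid-binding protein gene Crabp2 was at 252 and 0.0295 ± 0.0417, the neurofilament gene Nefl at 189 and 0.416 ± 0.0341, and Afp at 338 and 1.33 ± 0.176. Hba-x was at 1695 at E11.5 and listed at 0 at E18.5, at least 13558-fold lower. Of the markers of other tissues, lower ones numbered 12 of 27 mesenchymal (limma, 22 tested, 2 rose and 20 fell, as many adjusted over the list alone), 13 of 15 erythroid (limma, 11 tested, 1 rose and 10 fell, as many adjusted over the list alone) and 8 of 15 neural crest and glial members (limma, 10 tested, 3 rose and 6 fell, as many adjusted over the list alone), with 2 neural crest and glial members and 1 erythroid member higher. The leukocyte list had 2 of 15 members lower and 1 higher (limma, 14 tested, 2 rose and 9 fell, as many adjusted over the list alone), and with libraries set to the same total the median log2 difference of leukocyte, E18.5 against E11.5, was -1.05 in place of -0.57. Vim, the gene of the intermediate filament protein vimentin (ENSMUSG00000026728, chromosome 2, 13573927 to 13582826), was at 112 and 36.6 ± 0.0653.

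In all 1545 genes were higher and 1120 lower, and limma called 4718 that rose and 4802 that fell, 1859 and 1578 of them at least 2-fold. With libraries set to the same total they were 962 higher and 2766 lower, and other pseudocounts, minimum levels and folds gave 713 to 2322 higher and 408 to 2090 lower. Against E13.5 in place of E11.5, a comparison chosen after seeing the data, the number of genes higher, E18.5 against E11.5, became 794 and the number of genes lower, E18.5 against E11.5, became 445.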

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

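The limma counts, the recovered libraries and the settings without E11.5 were chosen after seeing the data. No paired analysis was possible because each stage had 1 deposited column and the recovered libraries carry only a number that ties no library to another stage. Settings for replicate columns were not run, since the deposited values held none, and the minimum values do not enter list medians. The upper-quartile scaling, the pseudocount of 0.1, the scaling without E11.5 and the removal of mitochondrial, histone, predicted and pseudogene names kept each count of genes they were run on within 1.5 times. Same-total scaling moved the median of all genes by -0.11, -0.41, 0.11 and -0.46 in the order E13.5 against E11.5, E15.5 against E13.5, E18.5 against E15.5 and E18.5 against E11.5. Its share of higher genes was 12.3% at E15.5 against E13.5 (71.1% in the main analysis), 66.1% at E18.5 against E15.5 (53.2%) and 25.8% at E18.5 against E11.5 (58.0%). Without the top 100 genes, the shares at E15.5 against E13.5 and at E18.5 against E15.5 were 46.9% and 65.1%, and the shift at E15.5 was -0.13. The shift was then -0.09 at E18.5 against E11.5 and 0.09 at E18.5 against E15.5. The most abundant genes thus carried most of the same-total shift at E15.5 against E13.5 and at E18.5 against E11.5. Acinar digestive enzymes alone took 1.92% of FPKM at E13.5 and 23.7% at E15.5. The cause of the remaining shifts and shares, and of the shift at E18.5 against E15.5, was not tested.

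With the same total, 190 genes were higher and 1357 lower at E15.5 against E13.5, 534 lower at E18.5 against E15.5, and 962 higher and 2766 lower at E18.5 against E11.5. The number of changed genes highest at E11.5 was then 3607, the number of changed genes highest at E13.5 922, and the number of changed genes highest at E15.5 524. Without the top 100 genes, 356 were higher and 403 lower at E15.5 against E13.5. A looser or stricter rule moved counts by its own construction. Higher and lower genes in the order of comparisons above were 1635 and 1520, 1299 and 794, 1766 and 1696, 2322 and 2090 at 1.5-fold, and 282 and 411, 126 and 24, 230 and 100, 713 and 408 at a log2 difference of 2. At a minimum of 20 FPKM they were 439 and 336, 316 and 92, 389 and 497, 753 and 483, with genes highest at each stage in turn numbering 627, 169, 793 and, as the number of changed genes highest at E18.5, 575. With no minimum, 1294 were higher and 1699 lower at E13.5, 348 lower at E15.5, 1425 higher at E18.5 against E15.5 and 1950 lower against E11.5, and those highest at E11.5, E13.5 and E18.5 were 2636, 492 and 2033. With a pseudocount of 5, counts were 529 and 556, 334 and 95, 497 and 495, and 685 lower at E18.5 against E11.5, with 914 highest at E11.5 and 195 at E13.5. Among the 3 later stages alone, 402, 897 and 1077 were highest at E13.5, E15.5 and E18.5.

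The number of lists with a median of 1 or more either way, E13.5 against E11.5, was 21 with a pseudocount of 0.1 (13 in the main analysis). The number of lists with a median of 1 or more either way, E18.5 against E15.5, was 5 with a pseudocount of 5, 17 with members at 5 FPKM or more and 7 by the mean (11). The median log2 difference of endothelium, E18.5 against E15.5, turned to -0.93 with members at 5 FPKM or more, of its 3 measured. The median log2 difference of progenitor transcription factors, E18.5 against E11.5, turned to -0.17 without members shared with other lists. Genes detected at 0.1 FPKM were 20479, 19118, 19570 and 19707 over the stages, and at 5 FPKM 6742, 6707, 6746 and 6891. Pearson's r with a pseudocount of 0.1 was 0.789, 0.702 and 0.680 for E11.5 with E13.5, E15.5 and E18.5. Over genes at 10 FPKM or more it was 0.716, 0.548 and 0.494, with 0.895, 0.802 and 0.858 for E13.5 with E15.5, E13.5 with E18.5 and E15.5 with E18.5. In place of the number of genes higher, E18.5 against E11.5, and the number of genes lower, E18.5 against E11.5, a comparison of E18.5 with E13.5 gave 794 and 445. The cause was not tested.

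Leaving out each recovered library, where the lone library is assumed to vary like the other stages, gave limma counts at 2-fold of 963 to 1038 rising and 1417 to 1438 falling at E13.5, 517 to 585 and 251 to 275 at E15.5, 1173 to 1212 and 792 to 824 at E18.5 against E15.5, and 1832 to 1872 and 1577 to 1593 against E11.5, all within 1.5 times the counts with both. The recovered libraries of a stage were nearly alike, so leaving out either could move these counts little. Depth limits low genes most, and abundant genes had no limma test because their means could not be split.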

Other observations

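Other gene groups were compared between stages as well. At E13.5 against E11.5, 3 of 28 Wnt genes were lower, 1 higher and 24 neither, with a median log2 difference of -0.79 (limma, 25 tested, 7 rose and 14 fell, as many adjusted over the list alone). The median log2 difference of Wnt targets and components, E13.5 against E11.5, was -0.08 over members at 5 FPKM or more. In the same comparison 17 of 27 mesenchymal, 4 of 7 mesothelial and 8 of 15 neural crest and glial markers were lower, and the cells that held these signalling transcripts are not known. The Wnt inhibitor gene Sfrp1 was at 42.0 ± 1.66 and 1.77 ± 0.0286 FPKM and the ligand gene Wnt4 at 36.2 ± 0.948 and 1.52 ± 0.0733. Of 95 oxidative phosphorylation genes 14, 5 and 1 were higher and 0, 0 and 13 lower by the rule of size in the 3 comparisons of consecutive stages, so most passed in none. Their median was 0.64 at E13.5 against E11.5 (limma, 67 tested, 48 rose and 5 fell, 51 and 6 adjusted over the list alone). The median log2 difference of oxidative phosphorylation, E15.5 against E13.5, was 0.55 (limma, 67 tested, 52 rose and 4 fell, 53 and 4 adjusted over the list alone) and turned to -0.04 with libraries set to the same total. At E18.5 against E15.5 it was -0.58 (limma, 67 tested, 5 rose and 50 fell, as many adjusted over the list alone). Genes of the FGF list were higher at E18.5 against E15.5 in 7 of 16 members (limma, 15 tested, 11 rose and 2 fell, as many adjusted over the list alone), with the receptor genes Fgfr3 at 2.22 ± 0.0137 and 9.93 ± 0.00578 and Fgfr2 at 3.29 ± 0.135 and 11.4 ± 0.407. The complement gene C1qa was at 5.13 ± 0.499, 13.3 ± 1.33, 176 ± 1.32 and 66.4 ± 3.83 FPKM over the 4 stages.

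Tests on the embryonic globins, on Y-linked and Xist reads, on ribosomal protein genes that share few windows, on shared coding genes, on genes matched in transcript length, and on marker lists without a minimum were chosen after related values had been seen. The first pattern was the transcripts of other tissues at E11.5, which otic epithelium or sensory neurons in the collection may have brought, and a later stage in the file was argued against by the embryonic globins, with a median log2 difference to E13.5 of -6.70. Otic epithelium stays undecided: 12 markers at 1 FPKM or more in any stage, 6 of them lower by the rule of size and Tbx1 the most abundant at 22.0 and 0.902, had a median of -2.51 (bootstrap interval -3.42 to -1.55), but this minimum favours genes present at E11.5, and all 16 names without it gave -1.76 (-3.10 to -0.88), an interval that reaches above the predicted bound of -1. Sensory neurons stay undecided alike, with -1.74 over 13 markers and -1.26 (-2.05 to -0.78) over all 17 found. Of the 13 only 4 were lower by the rule of size, among them Map1b, the most abundant, at 77.5 and 6.51, while Ret went the other way, at 0.254 and 2.89, and Celf3 had a log2 difference of -0.16. Pdx1 stood at 3.71%, Foxa2 at 5.16% and the epithelial Cdh1 at 9.70% of their E13.5 levels, while Epcam stood at 38.4% and the progenitor factor gene Sox9 at 40.2%, and whether other cells in the collection, for which no sort or gate is named, or a difference between stages lies behind this stays open.

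The second pattern was the lower ribosomal protein transcripts at E18.5, where the list had a median log2 difference of -1.45. Loss of short transcripts was argued against as the whole cause, since 1984 other coding genes of 712.8 to 4072.6 exon bases had a median of -0.22 (bootstrap interval -0.25 to -0.19), above the predicted bound of -0.4, but their median transcript had 1534 bases against 780, and 732 genes matched on transcript length (median 1005 bases) had -0.35 (-0.41 to -0.29), which reaches past that bound and leaves a part open. Reads shared with pseudogenes or paralogs were argued against as the whole cause, since the 13 ribosomal protein genes sharing under 10% of their windows had a median of -1.30, near the -1.41 of the 20 sharing at least 50%. Other coding genes sharing at least 50%, 253 in number, had a median of -0.15 (-0.33 to -0.02), above the predicted bound, while all 822 such genes, coding or not, did not decide it, with a median of -0.38 and an interval of -0.44 to -0.31 that reaches past it, the requirement on intervals having been added after that prediction was written. Other lists were higher at E15.5 and lower at E18.5 as well. Mitochondrially encoded genes had medians of 0.95 at E15.5 against E13.5 and -0.78 at E18.5 against E15.5. Replication-dependent histones had 0.57 and -0.83. With libraries set to the same total these were 0.37 and -0.61, and 0.14 and -0.67. A cause common to these lists, in the cells or in the libraries, was not tested. A part played by transcript length or sharing, or a change with stage, stays open.

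The third pattern was the close likeness of the 2 recovered libraries of each stage. Separate pools of embryos may differ in their mix of sexes, yet the log2 ratio of Y-linked to Xist reads differed within E15.5 and E18.5 by at most 0.129. The ratios themselves were -2.86 and -2.73 at E15.5 and 1.45 and 1.56 at E18.5, which argued against separate pools there, large pools of balanced sexes included, since these would give like ratios at both stages. At E11.5 and E13.5 the ratios differed within a stage by at most 0.0567, and as those stages were also near each other, separate large pools stay open there. The mix of sexes is confounded with stage in every comparison that involves E15.5 or E18.5. No biological explanation was tested.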
